A study of Mus musculus with 2 samples.

How the data were processed

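The data are polyA-selected, strand-aware RNA sequencing libraries of total RNA from mouse pituitaries at embryonic day E12.5, per the labels' protocols, with 1 wild-type and 1 Dyrk2 knockout library. Group membership was taken from the genotype label of each sample. How many embryos were pooled in a library, and their sex, are not given in the sources used here.

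The authors deposited 1 table per library with an Ensembl gene identifier, the summed exon length of the gene and its FPKM (fragments per kilobase of exon, scaled to the fragments counted in the library) to 2 decimals, per the file headers. Cutadapt 1.9.1, HISAT2 2.0.1 and the genome build GRCm38 are named in the submitters' processing notes. The tool that counted fragments, its use of strand, the annotation release and any filter are not given in the sources used here. Both tables hold the same 55401 genes. FPKM multiplied by exon length sums to the same constant in both, so the values were already scaled to the fragments counted in genes, and abundant transcripts or a difference in total RNA per cell can shift all other genes. FPKM of overlapping genes, close paralogs and pseudogenes depend on how shared fragments were assigned. Genes with under 200 bases of exon receive large FPKM from few fragments.

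The comparison had been planned for counts scaled by a trimmed mean, with deposited FPKM to be used as they stand if the tables held no counts. They held FPKM, so the values were used as deposited. Depth was recovered from the values: FPKM multiplied by exon length moves in steps of 1 fragment. The totals that make these steps whole were 20045004 counted fragments for the wild-type and 20115883 for the knockout library. All 1512 and 1372 values checked (at most 100 fragments, rounding error under 0.05 fragment) were whole within 0.1 fragment. These fragments were used for exact 95% Poisson intervals of FPKM, exact 95% Clopper-Pearson intervals of the ratio, and bounds for genes at 0 in 1 library. The intervals were added after the data were examined, cover counting error only, and carry no information on the spread between embryos. No count model was used.

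Symbols, gene types and coordinates came from GENCODE M21, an annotation of GRCm38, by gene identifier. Of the 55401 genes, 55141 matched and 260 did not. For 107 identifiers that share a symbol with another, the identifier with the higher mean FPKM stood for the symbol.

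Genes with at least 1 FPKM in at least 1 library were kept. The log2 ratio of each was taken as knockout over wild type after adding 0.5 FPKM to both. This understates the change of weakly expressed genes, so fold values in the text are plain ratios of FPKM with their intervals. A gene at 0 in 1 library was given a bound against a floor of 3 fragments, which leaves out the counting error of the other library. Counts of genes within or beyond a fold threshold use the log2 ratio with 0.5 FPKM added, and describe size only. The rank of a gene's ratio was taken among the 500 genes nearest in mean expression.

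Gene lists, 34 in all, were fixed before the data were examined. For each list with at least 4 members above the filter, the median log2 ratio was placed among the medians of 10000 random lists of equal size, matched in 20 bins of mean expression. A list is said to stand apart in the lowest or highest 2.5%. The percentile describes these 2 libraries and is not a p-value. The symbol Ahsp had no match, Ero1a was matched through its older symbol, and Cyr61 and Ccn1, which name 1 gene, were counted once.

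Genes named in the text followed a rule also fixed beforehand: Dyrk2 and its family, the 12 highest and 12 lowest ratios among genes of at least 5 FPKM in at least 1 library, and the 5 largest FPKM differences each way. From each list came up to 6 members with the largest difference of at least 1.5-fold and the 4 most expressed. Pomc, Gh, Prl, Lhb, Gli2, Esm1, Gm47434 and those genes of the closing observations that the rule does not cover were chosen after their values were seen.

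The steps were tested on simulated counts for all 55401 genes, with 200 genes changed, at set depths near those of the wild-type and knockout libraries. Changed genes were drawn from those of at least 2 FPKM in the wild-type library, and none was simulated as present in the knockout library only. In that comparison the depths were recovered with ratios to truth of 1.00 and 1.00. Of the genes changed 2.5-fold, 91% came out at 2-fold or more, and of those changed 5-fold, 100%. Counting error alone put 89 of 13730 unchanged genes at 2-fold or more, the intervals held the true ratio for 95.4% of unchanged genes, and 4.5% of 200 unchanged lists of 15 genes fell in the outer 5% of random lists. The simulated genes varied independently and these lists were drawn at random. That share therefore does not tell how often lists of genes that vary together would stand apart.

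Alternatives fixed beforehand were pseudocounts of 0.1 and 2, a filter of 5 FPKM and none, thresholds of 1.5-fold and 3-fold, protein-coding genes only, intervals beyond 2-fold, unmatched random lists, list means, and 3 other scalings computed on FPKM (median of ratios, upper quartile, and totals without haemoglobin, mitochondrial and the 20 most abundant genes). Scaling to the total, also fixed beforehand, is that of the deposited values. The upper-quartile and reduced-total scalings were fixed beforehand for the counts of genes only, and were added for single genes after the data were examined. Scaling by a trimmed mean of log ratios, a minimum exon length, and 3 restrictions of list members were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.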

Results

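The series holds RNA sequencing of the embryonic mouse pituitary at embryonic day E12.5, the stage at which Rathke's pouch, the oral ectoderm that forms the anterior lobe, holds mostly dividing progenitors and its earliest hormone cells. Total RNA of wild-type embryos was set beside that of embryos lacking Dyrk2, a protein kinase. The title of the series places the experiment among questions on primary cilia, cell identity and vessel growth in this organ. There was 1 library per genotype. The deposited values correspond to 20045004 counted fragments in the wild-type library and 20115883 in the knockout library, at which 1 fragment on a 1 kb gene equals 0.0499 and 0.0497 FPKM. With 1 library on each side, no difference below has a replicate check and no p-value was computed. The 95% intervals cover counting error only, not the spread between embryos, dissections or library preparations.

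Dyrk2 itself was the gene to examine before any other. Dyrk2 (ENSMUSG00000028630) lies on the minus strand of chromosome 10 from 118855603 to 118870209 in GRCm38. It measured 11.5 FPKM (95% Poisson interval 10.9 to 12.1) in the wild-type library and 1.93 FPKM (1.70 to 2.19) in the knockout library. The knockout library thus held 16.8% of the wild-type level (14.6% to 19.2%), a log2 ratio of -2.31, and all 500 genes nearest in mean expression had a higher ratio. Where on the transcript the remaining fragments lie was not analysed here. The other kinases of the family were close to level, with Dyrk1a at 12.6 and 12.8 FPKM and Dyrk1b at 17.5 and 16.2 FPKM. Hipk2, at 10.2 and 14.0 FPKM, was the furthest from equality of those above the filter. An unclassified transcript on the same strand, Gm47434, from 118832588 to 118835106, was at 0 in the wild-type library and at 4.30 FPKM (218 fragments) in the knockout library. Its end nearer to Dyrk2 lies 20.5 kb beyond the 3' end of that gene, and it was singled out after its values were seen. Set against a floor of 3 fragments it was 72.4-fold higher, and the lower limit of its 95% counting interval was 58.4-fold. The log2 ratio of Gm47434 ranked 1 from the top among all 14000 genes compared.

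**Figure D1:**
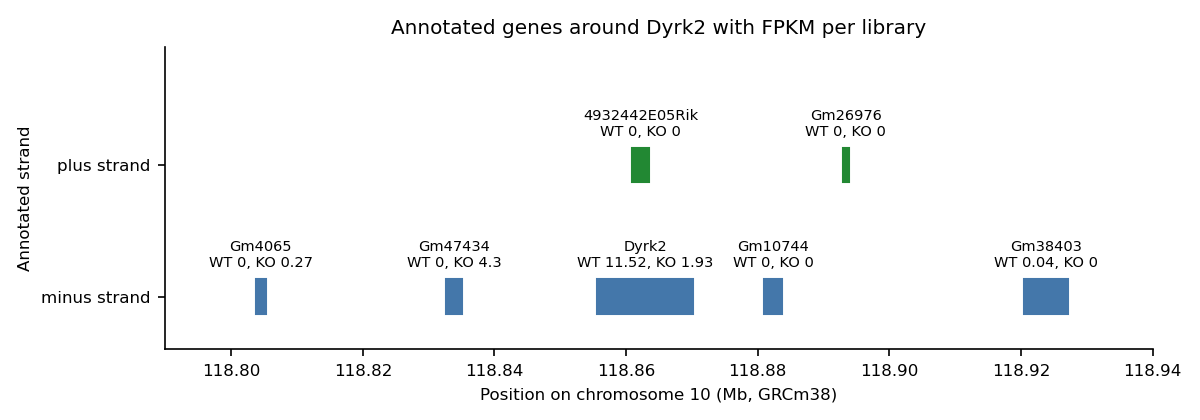
Annotated genes around Dyrk2 on chromosome 10 by strand, with position in Mb on the horizontal axis and the FPKM of the wild-type (WT) and knockout (KO) library above each gene. Dyrk2 was at 11.5 and 1.93 FPKM, and Gm47434 at 0 and 4.30 FPKM.

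Most genes were at similar levels in both libraries. Of 14000 genes with at least 1 FPKM in at least 1 library, 93.4% lay within 1.5-fold after 0.5 FPKM was added to both values, 120 were at least 2-fold higher in the knockout library and 265 at least 2-fold lower. Counts of genes by fold rest on values with this addition throughout, and fold values of single genes on plain ratios. Among protein-coding genes of at least 5 FPKM in at least 1 library, the lowest log2 ratios with the addition belonged to Acta2, the smooth muscle actin, at 25.7 and 1.58 FPKM, and to Chga, which encodes the granule protein chromogranin A, at 94.9 and 10.8 FPKM. The highest belonged to Aldh1a3, a retinoic acid-forming enzyme, at 2.94 and 14.6 FPKM. The sizes of these counts rest strongly on short and weakly counted genes: 60 of the 120 and 99 of the 265 have under 200 bases of exon. The counting interval lay wholly beyond 2-fold for 37 higher and 116 lower genes, and log2 FPKM correlated at r = 0.976 across genes, which are not independent replicates.

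**Figure D2:**
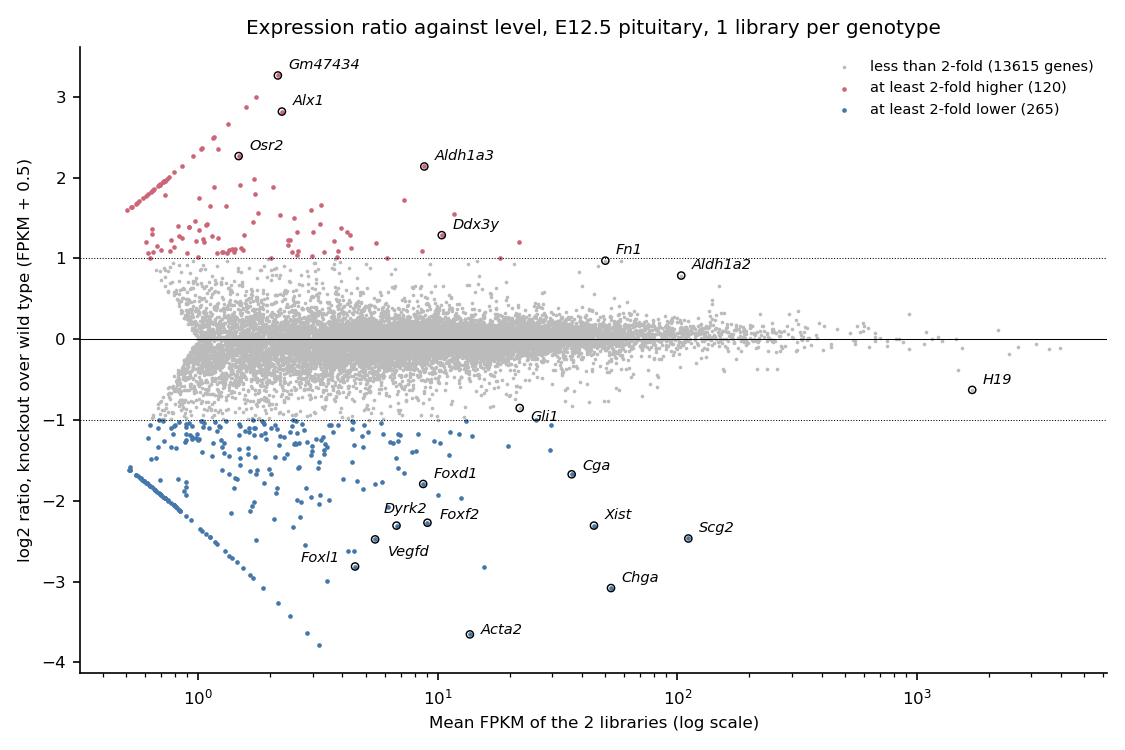
Log2 ratio of knockout over wild-type FPKM (0.5 added to both) against the mean FPKM of the 2 libraries on a log scale, with 1 point per gene for 14000 genes and dotted lines at 2-fold. The 265 genes at least 2-fold lower include Acta2, Chga, Scg2 and Dyrk2, and the slanted edges at low level are genes at 0 in 1 library.

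Hedgehog targets were lower in the knockout library. Of 13 listed genes, 10 passed the filter, and 7 of those were at least 1.5-fold lower. The forkhead genes Foxl1, Foxf2 and Foxd1, which respond to Hedgehog signals in mesenchyme, were 11.0-fold (95% interval 7.97 to 15.5), 5.51-fold (4.58 to 6.70) and 3.80-fold lower (3.39 to 4.27). Hhip, an antagonist that binds Hedgehog ligand, measured 3.65 and 1.05 FPKM. Gli1, the transcription factor most used as a readout of the pathway, measured 28.4 and 15.5 FPKM, a 1.83-fold lower level (1.72 to 1.95). The receptor gene Ptch1 was 1.43-fold lower (1.38 to 1.48). Osr2, a regulator of palate and limb mesenchyme, went the other way, at 0.18 and 2.77 FPKM. The list had a median log2 ratio of -1.13, and none of 10000 random lists matched on expression had a median as low. Without its forkhead members the median was -0.85, and markers of mesenchyme, the tissue that expresses several of these genes, also had a lower median, -0.34.

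The genes that carry the Hedgehog signal did not share this pattern. Of 16 measured components, 14 lay within 1.5-fold with 0.5 FPKM added, among them the transducer Smo at 50.5 and 53.7 FPKM. The co-receptor genes Boc and Gas1 were 1.82-fold (1.53 to 2.18) and 1.66-fold higher (1.52 to 1.81). Gli3, whose product is the main repressor of the pathway, measured 11.4 and 17.2 FPKM, and Gli2 measured 4.50 and 6.97 FPKM, both beyond 1.5-fold as plain ratios. The median of the components was 0.08, at percentile 98.2 of random lists, and with a filter of 5 FPKM it no longer stood apart, at percentile 96.9.

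Transcripts for building the primary cilium, the cell's signalling antenna, differed little. All 49 listed genes for its structure and transport were measured and all 49 lay within 1.5-fold, with log2 ratios from -0.39 to 0.30. Of these ratios, 35 were below 0 and 14 above, and the counting interval excluded 1 for 18 lower and 4 higher genes. The transport gene Ift20 measured 24.4 and 24.3 FPKM, and Kifap3, a subunit of the kinesin motor, 28.0 and 27.0 FPKM. The median of -0.07 stood at percentile 5.02 of random lists, and at 2.34 with a filter of 5 FPKM. The 10 genes of cilium disassembly, such as Aurka at 24.3 and 28.2 FPKM, also all lay within 1.5-fold. Cilia themselves were not measured by these libraries.

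Among pituitary genes, the progenitor factors lay near level while secretory genes were far lower in the knockout library. All 20 progenitor transcription factors were measured and 19 lay within 1.5-fold, with Pitx1 at 250 and 227 FPKM and Lhx3, a pouch determinant, at 73.0 and 85.9 FPKM. Lhx4, its close relative, was 1.56-fold lower (1.41 to 1.73). The list median was -0.07, at percentile 1.15 of matched random lists, but it did not stand apart when the random lists were drawn without matching, by its mean or without members shared with other lists.

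Regulators of hormone cell lineages diverged more. Neurod1, a factor of early corticotroph differentiation, was 4.69-fold lower (3.30 to 6.80), at 3.33 and 0.71 FPKM. Insm1, a neuroendocrine repressor, was 1.64-fold lower (1.51 to 1.78), and Gata2, a factor of gonadotrophs and thyrotrophs, measured 26 and 16.4 FPKM. Gata3 was 2.86-fold higher (2.13 to 3.85) from a low level of 0.80 FPKM. The median over 9 measured members was -0.29, at percentile 0.23. The list did not stand apart by its mean or without the members it shares with other lists.

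Of the hormone and secretory genes, 7 of 10 measured were at least 1.5-fold lower and none was higher by that much. Chga was 8.80-fold lower (8.08 to 9.59). Scg2, which encodes another granin of secretory granules, measured 189 and 33.7 FPKM, a 5.59-fold lower level (5.31 to 5.89). Cga, the shared alpha subunit of the glycoprotein hormones, measured 55.4 and 17.0 FPKM, a 3.25-fold lower level (2.87 to 3.69), and Pcsk1, a prohormone convertase, 2.45 and 0.40 FPKM. Pomc, the precursor of adrenocorticotropin, did not differ, at 8.67 and 8.71 FPKM. The median was -1.36, below that of every random list. Transcripts of the late hormones Gh, Prl and Lhb were at 0 in both libraries, where the floor of 3 fragments equals 0.15 FPKM on a 1 kb gene.

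**Figure D3:**
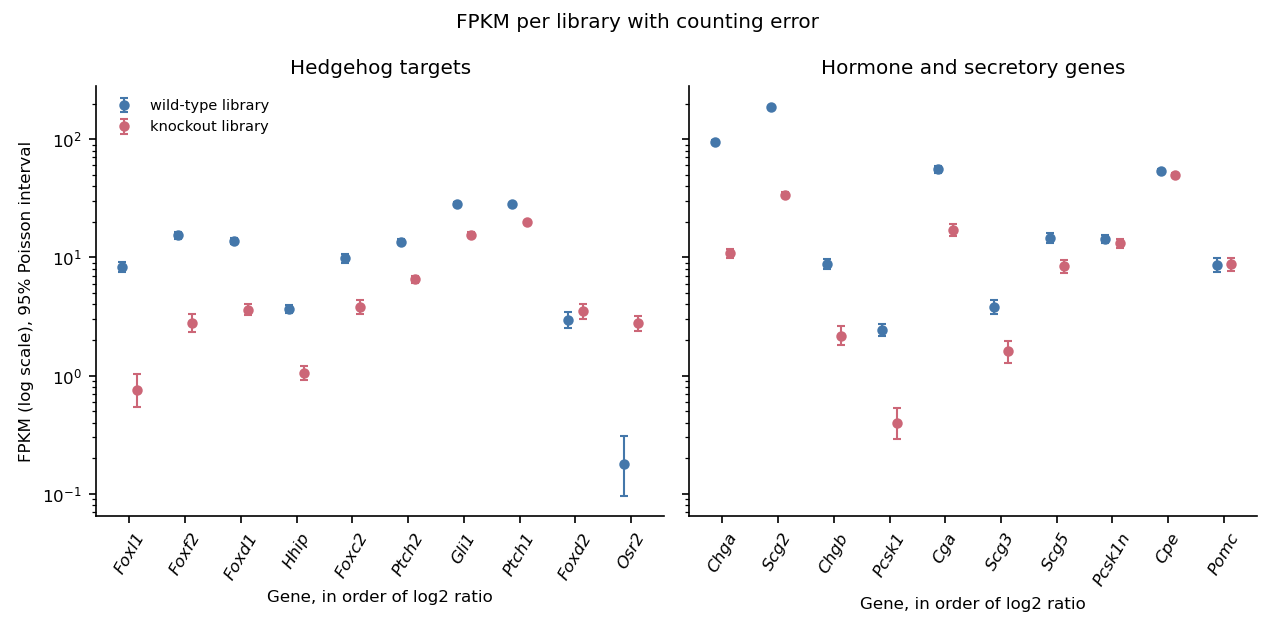
FPKM of the 10 measured Hedgehog targets and the 10 measured hormone and secretory genes on a log scale, with 1 point per library and bars for the 95% Poisson interval of counting. Knockout points lie below wild-type points for Foxl1 (0.75 against 8.28 FPKM) and Chga (10.8 against 94.9 FPKM), while Pomc points coincide.

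Among vessel genes, the lists of endothelial markers and of pericyte and smooth muscle markers had medians on opposite sides. Endothelial markers were slightly higher in the knockout library as a list: 20 of 30 measured genes had log2 ratios above 0 and 10 below, and 29 lay within 1.5-fold, with Cdh5, an endothelial cadherin, at 24.1 and 28.1 FPKM and Plvap, a fenestral diaphragm protein, 1.32-fold higher (1.22 to 1.43). Flt4, a receptor for Vegfc and Vegfd, measured 1.98 and 3.76 FPKM, while Esm1, the lowest of the list, measured 1.21 and 0.66 FPKM. The median was 0.11, at percentile 99.98 of random lists.

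Angiogenic ligands went both ways. Vegfd was 7.30-fold lower (5.61 to 9.62), at 9.63 and 1.32 FPKM, and Angpt2, which modulates the Tek receptor, 2.42-fold lower (2.12 to 2.79). Angptl4 measured 5.58 and 3.50 FPKM. Adm, a vasoactive peptide gene, was 7.76-fold higher (4.14 to 16.2) from 0.34 FPKM, and Angpt1 measured 21 and 21.8 FPKM. The median over 18 members was -0.12, at percentile 2.77. It stood apart with a filter of 5 FPKM, with a median of -0.23, and without members shared with other lists.

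Markers of pericytes and smooth muscle, the contractile cells around vessels, were lower. Acta2 was 16.2-fold lower (12.7 to 20.9), Tagln, another contractile gene, 3.92-fold lower (3.13 to 4.98), and Pdgfrb, the growth factor receptor of pericytes, 2.08-fold lower (1.93 to 2.25). Notch3, a receptor of the same cells, measured 48.1 and 48.0 FPKM. Of 11 measured genes, 4 were at least 1.5-fold lower and none that much higher, and the median was -0.51, below that of every random list. Mesenchyme markers also had a lower median, -0.34, so the lower values cannot be assigned to cells around vessels alone.

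Mesenchyme and neural crest markers split. Of 22 measured genes, 6 were at least 1.5-fold lower and 4 at least 1.5-fold higher. The collagen gene Col1a1 measured 42.7 and 16.2 FPKM, and Twist1, a regulator of mesenchyme, was 2.30-fold lower (1.96 to 2.70). Tcf21 was at 1.61 FPKM and 0, 25.4-fold lower against a floor of 3 fragments, with a lower 95% counting limit of 20.2-fold. Against these, Alx1, a regulator of frontonasal mesenchyme, was 23.8-fold higher (15.3 to 38.4), at 0.18 and 4.29 FPKM, and Alx4 measured 0.49 and 1.51 FPKM. The median was -0.34, unchanged with Tcf21 at its bound and lower than in any random list, although by its mean the list did not stand apart.

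Neighbouring tissues were gauged with further markers. Cartilage genes had a median of -0.23 over 10 genes, at percentile 0.91, with Matn4 at 3.30 and 0.18 FPKM and Col2a1, the main cartilage collagen, at 141 and 121 FPKM. Oral and pharyngeal epithelium did not stand apart as a list (median -0.10), although Tbx1, a pharyngeal regulator, was 3.67-fold lower (2.82 to 4.89) and the keratin gene Krt15 was higher, at 0.28 and 1.55 FPKM. Hypothalamic and infundibular markers had a median of 0.03, and Bmp4, an infundibular signal, measured 6.50 and 10.5 FPKM. Neuronal markers had a median of 0.24, but the neurofilament gene Nefm was lower, at 16.8 and 9.19 FPKM. The neuronal median turned to -0.072 with a filter of 5 FPKM, and by its mean that list did not stand apart. Glial markers (-0.25) and macrophage markers (-0.18) did not stand apart, and only 1 of 16 skeletal muscle genes passed the filter.

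Transcripts of dividing cells were slightly and evenly higher in the knockout library. All 25 genes of S phase had log2 ratios above 0, with Pcna, the replication clamp, at 75.5 and 90.2 FPKM, and 23 of 25 mitotic genes did, with Top2a, a chromosome topoisomerase, at 58.1 and 68.5 FPKM. Their medians were 0.20 and 0.13, and no member of either list reached 1.5-fold. Of the cell cycle inhibitors, Cdkn1b measured 17.9 and 13.5 FPKM and Cdkn1c 830 and 1028 FPKM, and the list median was -0.16, at percentile 1.14. It did not stand apart against unmatched random lists, by its mean, with a filter of 5 FPKM (-0.068, percentile 11.6) or without members shared with other lists.

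In the Notch list 15 of 19 log2 ratios lay below 0, and the median of -0.14, at percentile 0.485, stood apart under every alternative run. Those alternatives include a restriction to members whose interval excludes 1, which selects the members that differ. Without members shared with other lists the median was -0.26. Among its members Heyl, a target gene active in perivascular cells, was 2.57-fold lower (2.33 to 2.83). In the BMP list (median 0.11, percentile 99.4) the antagonists Nog and Grem1 parted, at 1 and 2.26 FPKM and at 2.35 and 0.80 FPKM. In the Wnt list (median -0.05) Sfrp2, a secreted antagonist, was 2.36-fold higher (2.14 to 2.61) and Dkk1, another, 2.56-fold lower (1.53 to 4.39). With a filter of 5 FPKM the Wnt median turned to 0.114 and stood apart, at percentile 98.5. FGF targets (0.04), p53 targets (-0.02) and immediate early genes (-0.12) did not stand apart. Hypoxia and glycolysis genes had a median of 0.17, at percentile 99.98, with the lactate enzyme gene Ldha at 119 and 161 FPKM. Matrix genes had a median of -0.05 over members as different as Col6a1, at 11.5 and 4.06 FPKM, and the fibronectin gene Fn1, at 33.6 and 66.5 FPKM.

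The makeup of the 2 samples differed in blood and in sex. Erythroid markers had a median of -0.37, below every random list, with the embryonic globin gene Hbb-y at 1675 and 1285 FPKM, and haemoglobin genes took 0.167% and 0.128% of fragments. Xist, transcribed from the inactive X chromosome of females, measured 75 and 14.8 FPKM, while the Y-linked gene Ddx3y measured 5.83 and 14.95 FPKM. Transcripts of both sexes were thus in both libraries in different proportions, and every contrast between the genotypes is also a contrast between these mixtures. The median log2 ratio was -0.01 over 520 X-linked genes and -0.02 over 13443 autosomal genes. Mitochondrially encoded genes (median -0.01) took 1.59% and 1.54% of fragments. Stress genes had a median of 0.11, at percentile 98.4, with the small heat shock gene Hspb1 lower, at 6.19 and 2.60 FPKM, and Chac1, a target of the unfolded protein response, higher, at 0.46 and 1.06 FPKM. By their means, neither the stress nor the BMP list stood apart, and the stress list did not with a filter of 5 FPKM either, at percentile 97.3.

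Among genes outside these lists, Penk, the enkephalin precursor, was 7.94-fold lower (6.53 to 9.73) and Gnb3, a G protein subunit, 17.2-fold lower (11.0 to 28.6) in the knockout library. Sox14, a transcription factor of neurons, measured 7.59 and 0.82 FPKM. Aldh1a3 was 4.98-fold higher (4.37 to 5.69), its relative Aldh1a7 measured 3.09 and 11.4 FPKM, and Gsc, a craniofacial homeobox gene, 2.16 and 6.16 FPKM. In absolute level the largest deficit was that of H19, an imprinted non-coding RNA, at 2065 and 1337 FPKM. The largest surplus was that of Cdkn1c.

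**Figure D4:**
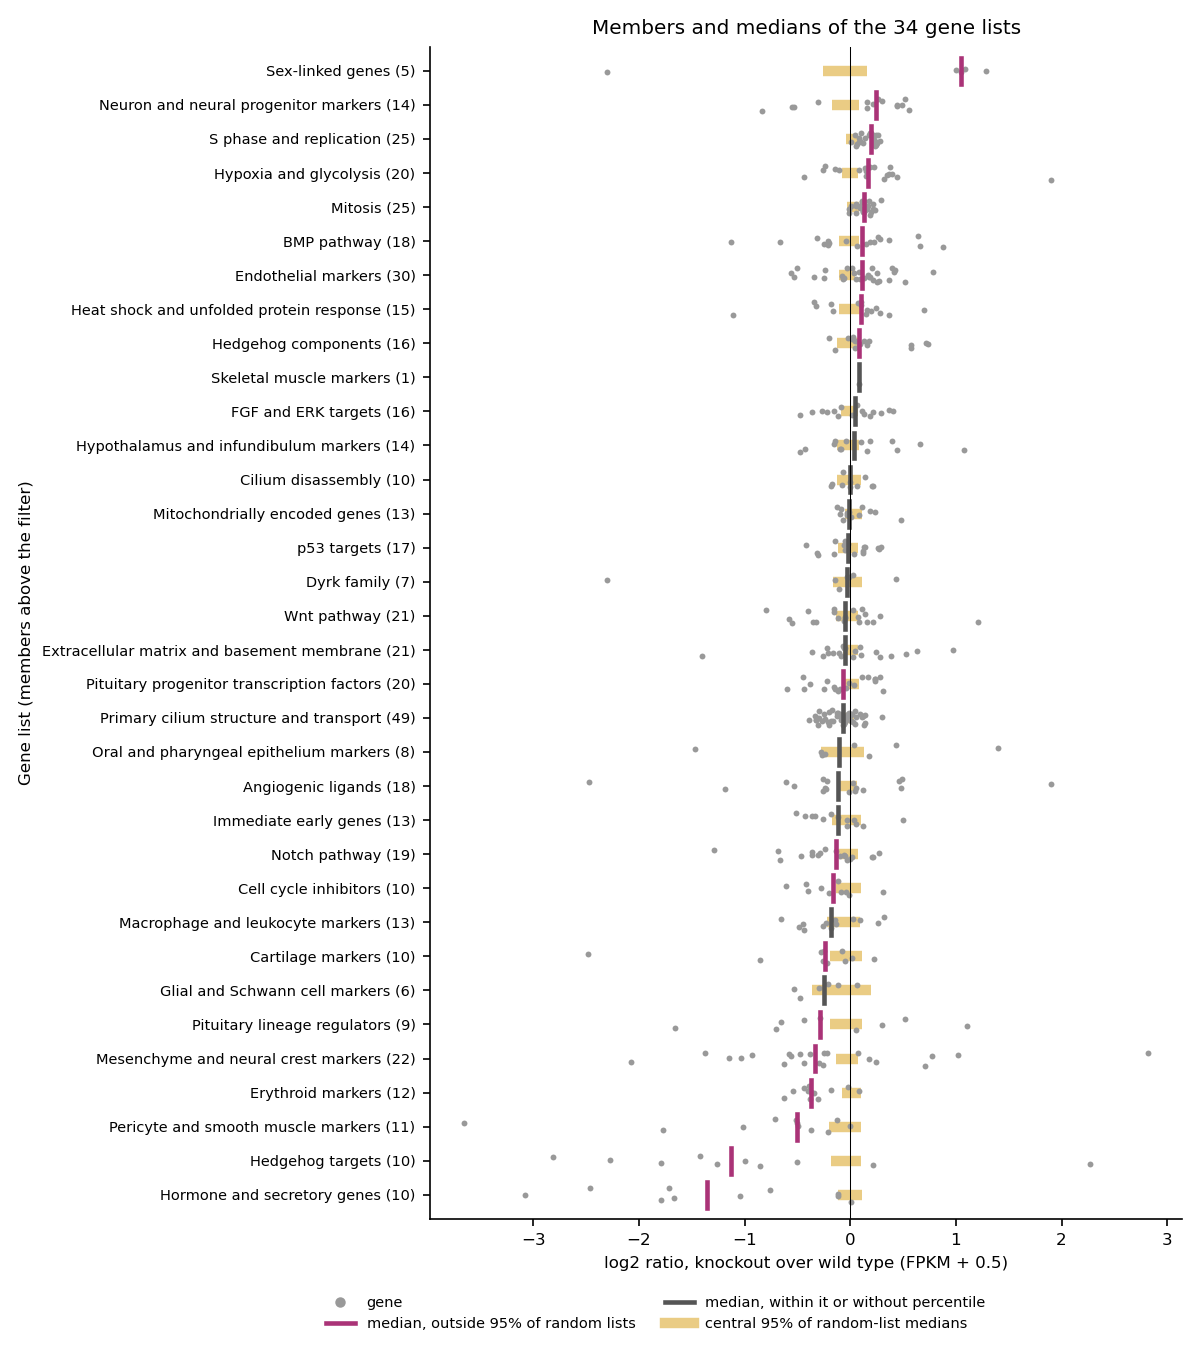
Log2 ratios (knockout over wild-type FPKM, 0.5 added to both) of the members of 34 gene lists, with 1 point per gene, the median as a vertical bar and the central 95% of random-list medians shaded. Medians range from -1.36 for hormone and secretory genes to 1.05 for sex-linked genes, and 19 of the 33 lists with a percentile stood apart.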

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

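The scaling by a trimmed mean of log ratios, the exon length minimum and the restrictions of list members were chosen after the data were examined. So were, for single genes, the upper-quartile scaling and the totals without abundant genes, which had been planned for the counts only. No paired analysis was possible because there was 1 library per genotype. The 4 scalings changed little: they multiplied the knockout library by 0.997 to 1.03 and left 119 to 130 genes at least 2-fold higher and 251 to 266 lower. The counts of 120 higher and 265 lower genes depended on how weak and short genes were treated. They were 169 and 376 with a pseudocount of 0.1, 20 and 83 with a pseudocount of 2, 17 and 69 with a filter of 5 FPKM, 217 and 410 with no filter, 46 and 125 over protein-coding genes, 60 and 166 with exon lengths of at least 200 bases, and 37 and 116 with the counting interval beyond 2-fold. Thresholds of 1.5-fold and 3-fold gave 289 and 52 higher and 638 and 127 lower genes. These shifts follow from how each alternative is built. The Dyrk2 log2 ratio was -2.52 with a pseudocount of 0.1 and -1.78 with 2. Log2 ratios of genes at 0 in 1 library follow the pseudocount. The Tcf21 log2 ratio was -4.10 with 0.1 and -0.85 with 2. Of 260 list values, 230 kept their side of the 2.5% limits, 15 no longer stood apart and kept their direction, 1 no longer stood apart and turned its sign, and 12 newly stood apart in the same direction and 2 in the other. Medians of Hedgehog targets (-0.85 to -1.26) and of secretory genes (-0.79 to -1.69) stood apart under every alternative run, as did endothelial and pericyte markers. The restriction to members whose interval excludes 1 selects the members that differ, so it is no check of any list. Without that restriction the secretory medians ran from -0.79 to -1.45. The lists of Hedgehog components (0.088) no longer stood apart and cilium genes (-0.077) and angiogenic ligands (-0.23) newly did with a filter of 5 FPKM. By the mean, progenitor factors (-0.063), lineage regulators (-0.20) and mesenchyme (-0.22) no longer stood apart. Without members shared between lists, progenitor factors (-0.026) and lineage regulators (-0.12) no longer did, while angiogenic ligands (-0.22) newly did. With unmatched random lists progenitor factors (-0.069) did not. Restricted to members whose interval excludes 1, cilium genes (-0.23) and angiogenic ligands (-0.24) stood apart, which selects the members that differ. The median of neuronal markers turned from 0.24 to -0.072 with a filter of 5 FPKM, and by its mean that list no longer stood apart. The Wnt median turned from -0.05 to 0.114 with that filter and then stood apart. Cell cycle inhibitors no longer stood apart with that filter (-0.068), by the mean, with unmatched lists or without shared members. Stress genes no longer did with that filter or by the mean, nor BMP genes by the mean. The Dyrk family (-0.31) and hypothalamic markers (0.114) newly did by the mean, and glial and macrophage markers with unmatched lists. Hypothalamic, macrophage, immediate early and cilium disassembly genes newly did when restricted to members whose interval excludes 1. Apart from the restriction to members whose interval excludes 1, the cause of these changes was not tested. Depth limits genes near 1 FPKM, and the single library per genotype limits every value.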

Other observations

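All tests in this part were chosen after the results they bear on were seen, and the genes here were picked from their values, so no group below is an independent theme. Genes for retinaldehyde dehydrogenases, which form retinoic acid, were higher in the knockout library. Aldh1a2, the most abundant of them, measured 76.0 and 132 FPKM in the wild-type and knockout libraries, a 1.73-fold higher level (95% counting interval 1.66 to 1.81), and Aldh1a1 measured 0.23 and 1.12 FPKM. Rarb, a receptor gene that retinoic acid induces, did not follow, at 13.8 and 13.1 FPKM, and Cyp26a1, which encodes a degrading enzyme, was at 1.06 and 0.48 FPKM. Among imprinted growth genes H19 was 1.54-fold lower (1.53 to 1.56), Igf2, its neighbour, 1.79-fold lower (1.71 to 1.87) and Zim1 2.11-fold lower (2.03 to 2.21), while Rtl1 was 1.53-fold higher (1.41 to 1.66), Dlk1 measured 555 and 638 FPKM and Plagl1 52.2 and 52.1 FPKM.

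Several neuroendocrine genes outside the lists were lower too. Ptprn, which encodes a granule membrane protein, was 5.30-fold lower (4.25 to 6.65), Scgn, a calcium-binding secretagogin, measured 5.12 and 0.46 FPKM, and Resp18 4.98 and 0.92 FPKM. Igsf1, whose human counterpart is mutated in central hypothyroidism, was 1.70-fold lower (1.64 to 1.77). In the connective tissue, the collagen VI genes Col6a1, Col6a2 and Col6a3 were 2.84-fold, 2.64-fold and 2.33-fold lower, and Mgp, an inhibitor of calcification, 4.15-fold lower (3.30 to 5.25). Ogn and Efemp1, which encode matrix proteins, were 2.24-fold (1.94 to 2.60) and 1.98-fold (1.70 to 2.32) higher.

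Regulators of regional mesenchyme, picked here by their values, lay on both sides. Pax1 was at 4.32 FPKM and 0, 130-fold lower against 3 fragments, with a lower 95% counting limit of 105-fold. Zic1 measured 2.81 and 0.98 FPKM. By contrast, Tbx22, Barx1 and Alx1 measured 0.06, 0.39 and 0.18 FPKM in the wild-type library. In the knockout library they measured 2.37, 3.02 and 4.29 FPKM. Less mesenchyme in the knockout tissue was not tested as an explanation. A different border of the dissected tissue could bring in facial or skull base mesenchyme, and it cannot be told apart from altered patterning: of 5 lists of neighbouring tissues (cartilage, oral epithelium, hypothalamus, neurons and glia) 2 stood apart, cartilage lower and neuronal markers higher. The neuronal list did not stand apart by its mean, or with a filter of 5 FPKM, where its median turned to -0.072. No biological explanation of this pattern was tested.

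For the lower secretory genes, less pituitary epithelium in the knockout tissue as the whole cause is argued against by the progenitor factors, whose median log2 ratio was -0.069 where the secretory median was -1.36. Younger knockout embryos may account for part of it. Adult beta-globin stood at 5.62% of embryonic beta-globin in the wild-type library and 5.19% in the knockout library, a log2 difference of -0.12, too small and without a replicate to decide. An effect of the genotype itself stays open and was not tested.

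Gm47434, read in the knockout library only, lies downstream of Dyrk2 on the same strand. Counting error is argued against by its 218 fragments, where the wild-type library has 0. A disturbance of most genes within 5 Mb of Dyrk2 is argued against as well. Of the other genes measured there, 95.8% lay within 1.5-fold, against 93.4% of all genes compared. Of those 48 genes, 2 differed at least 2-fold: Irak3, 4.70-fold higher (2.95 to 7.84) at 0.30 and 1.41 FPKM, and Gm25190, with 3 fragments and 0. A change confined to the stretch next to Dyrk2 cannot be judged, because Gm4065, Gm10744 and Gm38403 around it were below the filter. Transcription from the altered Dyrk2 allele that runs past its end may be the source, but Gm4065, the next annotated gene on that strand, reached only 0.27 FPKM (8 fragments, 0 in wild type), which leaves this open. How the allele was made is not given in the sources used here, and read positions were not analysed here.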
